A study of Mus musculus with 6 samples.

How the data were processed

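Gene expression was measured with Affymetrix HT_MG-430_PM arrays, which read transcripts through sets of short oligonucleotide probes (probe sets), in dendritic cells sorted from mouse spleen. Per the labels' protocols, spleens were digested with collagenase, CD11c-positive cells were enriched with magnetic beads, and cells carrying CD11c and MHC class II but not T cell receptor beta, CD19 or CD49b were sorted. Total RNA was isolated with a micro-scale column kit, and between 1 and 20 ng was amplified and biotin-labelled with NuGEN kits, per the labels' protocols. The 6 arrays fell into 2 genotypes by their labels, with 3 wild-type and 3 LKB1 knockout samples, each on 1 array. The labels do not say whether the samples of a genotype came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

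The deposited values were made with RMA and Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA gives log2 signals after background correction, normalization between arrays and summary over the probes of a set. The log2 scale of the deposited values is inferred from their range and the named method, since the sources used here do not state it. The settings of these steps and a genome build are not given in the sources used here, so no coordinates are printed. RMA draws low signals together, so changes of dim transcripts are understated.

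From the deposited log2 values, 104 control probe sets were left out and 45037 probe sets were tested. Probe sets were named through GEO's platform annotation: 28898 had 1 gene symbol, 551 had several and were not named, and 15588 were not listed there and stay unnamed here. Symbols were checked through gene identifiers against the gene table of GRCm38.p6, in which 28689 probe sets matched and 0 symbols changed. The named probe sets covered 17097 genes. Probe sets of some genes of interest, among them Ccr7, Siglech, Bst2 and Clec9a, have no single listed symbol and were not analysed here.

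Knockout was compared with wild type in 1 model over all 6 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with no covariate. Adjusted p-values are Benjamini-Hochberg values over the 45037 probe sets, the threshold was 0.05, and log2 differences are knockout minus wild type with their standard error. The moderated test had 7.81 degrees of freedom. The array's antigenomic control probe sets, which match no mouse transcript, set the background, and a probe set at or below the highest of them on every array of a group was treated as in the background there. For such a group, or one with some arrays there where the text says so, a bound is given as "at least N-fold", with the higher of the array's highest background signal and the probe set's own signal in its place. The number of arrays limits the precision of every value.

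Before the data were examined, 36 gene lists were fixed for pathways, dendritic cell subsets and other cell types that the sort could hold. They were LKB1 and AMPK kinases, CREB and CRTC targets, glycolysis, HIF-1 targets, the tricarboxylic acid cycle, the respiratory chain, fatty acid oxidation, sterol and fatty acid synthesis, LXR targets, ATF4 targets, MYC and ribosome biogenesis, cytosolic ribosome, mitochondrial ribosome, proteasome, lysosome and autophagy, NRF2 targets, the unfolded protein response, cell cycle, p53 targets and apoptosis, dendritic cell maturation, ligands acting on regulatory T cells, antigen presentation, interferon response, NF-kB and inflammatory genes, and handling stress. The cell lists were conventional dendritic cells of type 1 (cDC1) and type 2 (cDC2), plasmacytoid dendritic cells (pDC), macrophages and monocytes, B cells, T cells, natural killer cells, neutrophils, erythroid cells and platelets, stroma and endothelium, and sex genes. Each list was tested with limma's camera on 1 probe set per gene, that with the highest mean, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 35 lists. The sex gene list had 4 measured members, fewer than the 5 required, and was not tested. An estimated correlation and limma's fry were run beside it.

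The genes named in the text followed a rule fixed before the data were examined. It takes the 12 largest increases and the 12 largest decreases among genes that passed the threshold with all knockout values on one side of all wild-type values, 1 probe set per gene (the smallest p), and Stk11. It also takes up to 4 members of each list by smallest p, the 2 brightest members of lists of other cell types, and all sex genes. Genes named outside the rule were chosen after their values were seen, and the text does not mark all of them.

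The fit and the list test were tested on simulated data built on this comparison. Among 45037 probe sets, some changed by known amounts, limma called 3 of 67 at a change of 0.5 log2 units, 59 of 67 at 1 and 66 of 66 at 2, with 4 false calls among 132. A simulated list of 30 among 17097 genes shifted by 0.5 was called with the preset and the estimated correlation, and 0 unshifted lists were called. The simulated noise was drawn independently for each gene, so lists whose genes vary together were not tested. In the measured data the estimated correlation was 0.719 for the proteasome list and 0.21 for the cell cycle list.

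The alternatives were an intensity trend, robust empirical Bayes, 3 rescalings, 2 filters on dim probe sets, 1 probe set or the mean of all probe sets per gene, array weights, the replicate number as a block, each array left out in turn, another threshold and a fold floor, and for the lists also ranks, an estimated correlation and fry. Leaving out both arrays of a number and a filter on background were added after the data were seen.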

Results

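LKB1, encoded by Stk11, is a kinase that activates AMPK and related kinases. By its title, the study asked how LKB1 bears on the metabolic rest of dendritic cells and on immunity to tumours. Transcript levels were measured in splenic dendritic cells, the antigen-presenting cells that prime T cells, from C57BL/6 mice. The data comprised 3 wild-type and 3 LKB1 knockout arrays, with 1 comparison between them. Between 52.5% and 66.1% of probe sets in wild-type arrays and 59.4% and 74.7% in knockout arrays lay above the highest background control of their array, with more in the knockout at each replicate number. The 3' minus 5' signal of the beta-actin controls was -0.46 to -0.42 in wild type and -0.39 to -0.35 in knockout, while that of the Gapdh controls overlapped (1.18 to 1.21 and 1.14 to 1.20). Arrays correlated at 0.977 to 0.991 across probe sets.

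Stk11 was lower in the knockout arrays by 1 of its 3 probe sets. By the brightest of them, wild-type replicates 1, 2 and 3 read 8.38, 7.94 and 8.21, and knockout replicates read 7.21, 7.36 and 7.54. The means were 8.18 ± 0.222 and 7.37 ± 0.166 (SD, n = 3 each), a log2 difference of -0.81 ± 0.149 (SE; limma adjusted p = 0.0404). The dimmer probe sets, with wild-type means of 7.23 and 4.75, differed by -0.10 ± 0.10 and -0.17 ± 0.132 and did not pass. The labels do not say which part of the gene was deleted, and a probe set outside that part checks nothing. The call rested on single arrays: limma's adjusted p was 0.172 without wild-type replicate 1, 0.102 without wild-type replicate 3, and 0.182, 0.125 and 0.0610 without knockout replicates 1, 2 and 3. It was also lost after subtracting array medians (adjusted p = 0.0562) and with the mean of the probe sets (-0.36, adjusted p = 0.0739).

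Flrt3, Nrp2 and Ndnf had the largest named increases in the knockout, and 19 of 38 genes of the dendritic cell maturation list rose. Mmp12 and Dtx1 had the largest decreases among named genes that all arrays measured. Of 45037 probe sets, 854 passed limma's threshold, 608 higher and 246 lower in the knockout. They held 343 genes that were higher and 149 that were lower. At least 2-fold changes numbered 361 up and 99 down. The groups lay apart in all 854, which the threshold itself makes likely. They lay apart in 16.2% of all probe sets, where chance gives 10%. The count fell to 272 without wild-type replicate 1, 295 without knockout replicate 1 and 442 without knockout replicate 2. Arrays with the same number deviated together for numbers 2 and 3, and the count was 371 without both arrays numbered 2 and 479 without both numbered 3.

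**Figure D1:**
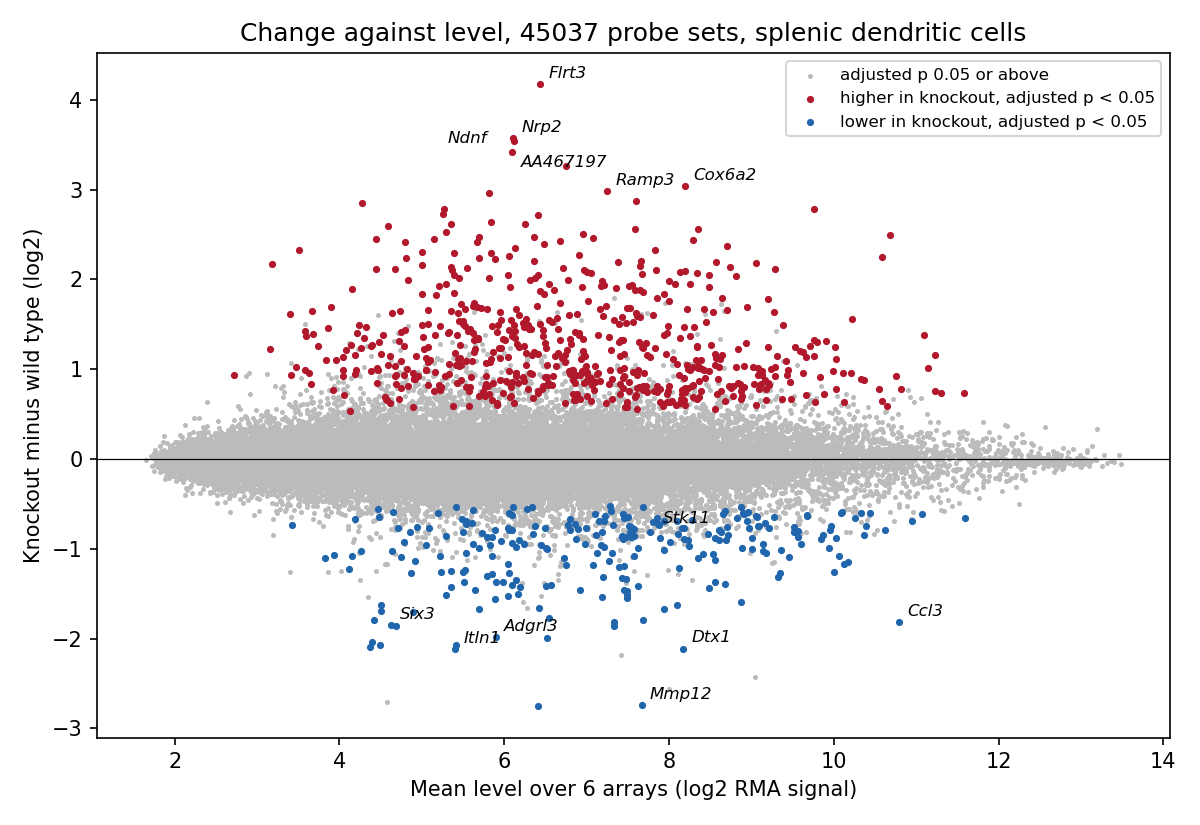
Each point is a probe set, with its mean log2 RMA signal over the 6 arrays on the x axis and its log2 difference, knockout minus wild type, on the y axis. Red points (608) are higher and blue points (246) lower in the knockout at a limma adjusted p under 0.05, and grey points did not pass.

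The largest increase was that of Flrt3, a membrane protein of cell adhesion and axon guidance, which was at least 13.66-fold higher in the knockout because all wild-type arrays lay in the background. Nrp2, a receptor of semaphorins and VEGF, was at least 8.82-fold higher, and Ndnf, a secreted neurotrophic factor, at least 8.80-fold. AA467197 was at least 8.32-fold higher, Atxn1 at least 5.31-fold, Il2ra, the alpha chain of the interleukin-2 receptor, at least 3.77-fold, 4931431B13Rik at least 3.75-fold and Gja1, the gap junction protein connexin 43, at least 1.92-fold. Measured on both sides, Cox6a2, a subunit of cytochrome c oxidase, rose 8.21-fold, from 6.68 ± 0.553 to 9.72 ± 0.0880 (SD, n = 3 each). Ramp3, a partner of calcitonin-family receptors, rose 7.91-fold and Glipr2 7.32-fold. Efnb2, the guidance ligand ephrin-B2, lay above background in 1 of 3 wild-type arrays and was at least 5.495-fold higher. The limma adjusted p-values of these 12 genes lay between 0.000652 and 0.00450, and each passed in the 6 fits that left out 1 array. Il2ra passed by 1 of its 2 probe sets, Gja1 by 3 of 5 and Atxn1 by 2 of 3, and the others by every probe set.

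The largest decrease was that of Mmp12, macrophage elastase, which fell 6.70-fold, from 9.04 ± 0.0710 to 6.30 ± 0.808 (SD, n = 3 each). Itln1, a lectin, lay above background in 1 of 3 knockout arrays and was at least 3.82-fold lower. Dtx1, a Notch target and regulator, fell 4.32-fold and Adgrl3, an adhesion receptor, 3.95-fold. Ccl3, a chemokine, fell 3.52-fold, Arhgap6 3.48-fold, Adgre1, a macrophage surface receptor gene, 3.42-fold, Bmp2 3.19-fold, Cd22, an inhibitory lectin, 3.09-fold and Hpgds, a prostaglandin D synthase, 2.94-fold. Six3 and Scel lay in the background in every knockout array and were at least 2.29-fold and 1.94-fold lower. The limma adjusted p-values ranged from 0.00251 to 0.0217. Without wild-type replicate 1, Mmp12, Ccl3, Arhgap6, Adgre1, Cd22 and Hpgds no longer passed (highest adjusted p = 0.0824), and without knockout replicate 1, Adgre1, Arhgap6, Bmp2, Cd22 and Six3 did not (highest 0.113). Bmp2 also did not pass without wild-type replicates 2 or 3 or knockout replicate 2 (0.0528, 0.0593 and 0.0735). With all arrays, Six3 passed by 2 of its 3 probe sets and Scel by 1 of 2, and the other decreases by every probe set.

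**Figure D2:**
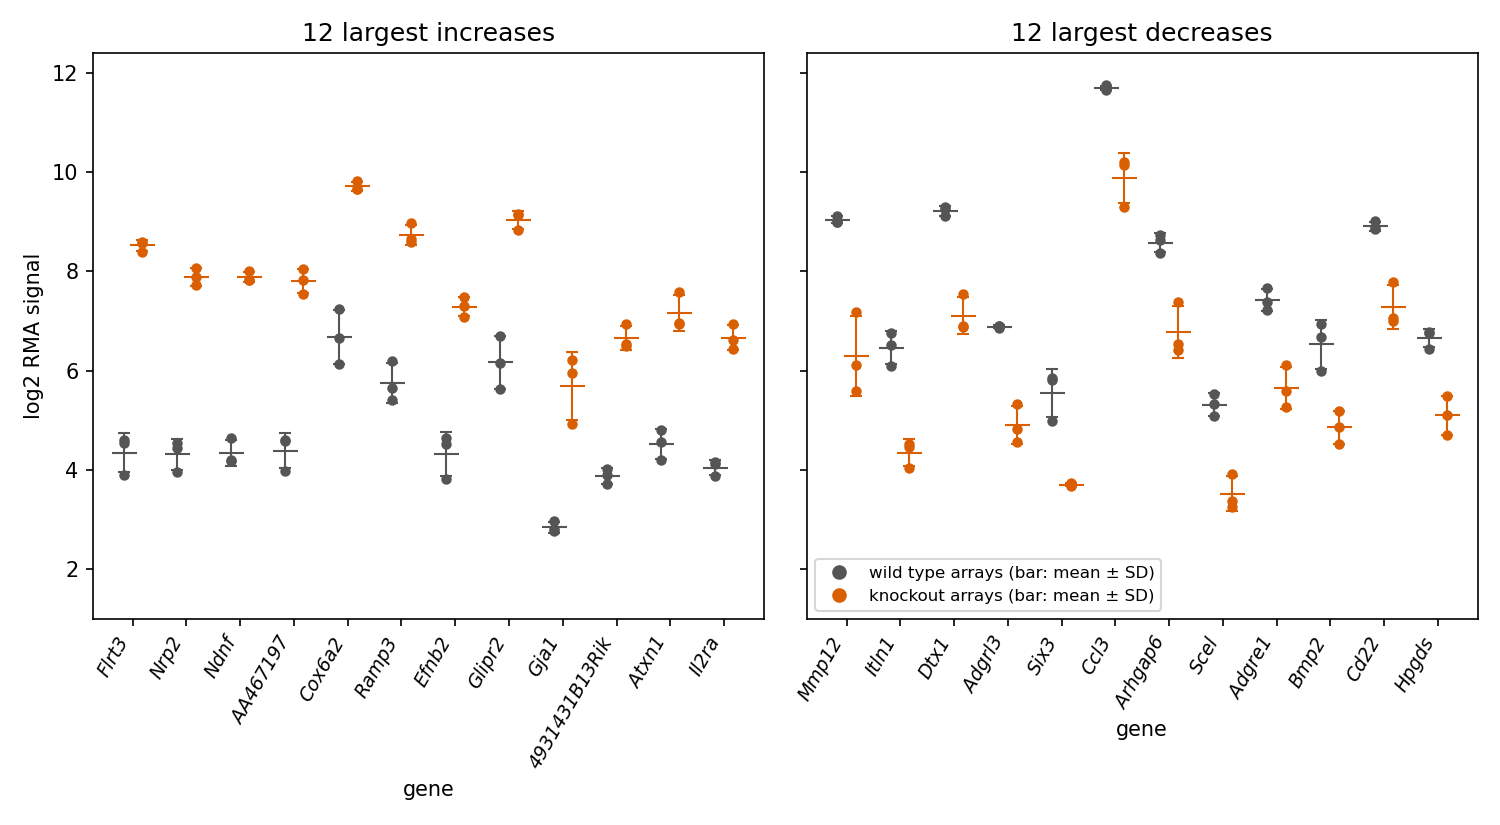
Log2 RMA signal (y axis) of the 12 genes with the largest increase and the 12 with the largest decrease (x axis), with a point per array and bars for mean ± SD (n = 3). Knockout arrays of Flrt3 averaged 8.52 against 4.35 in wild type, and those of Mmp12 averaged 6.30 against 9.04.

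Genes that rise in mature or migratory dendritic cells were higher in the knockout. Of 38 measured members 19 rose and 0 fell, and 28 rose when adjusted over the list alone. Among all 17097 genes in the list test, limma called 1.70% higher and 0.69% lower. Fscn1, the actin bundler fascin, rose by 2.49 ± 0.183 log2 units, Socs2, a feedback inhibitor of cytokine signalling, by 2.37 ± 0.192, and Stat4, a transcription factor of interleukin-12 signalling, by 2.20 ± 0.183. Il6 was at least 2.19-fold higher, with wild type in the background. Slco5a1, Ccl22, Serpinb9, Il15ra, Cd200, Tnfsf4 and Cd70 also rose, the last pair with 2 of 3 wild-type arrays above background. The costimulatory genes Cd80, Cd86 and Cd83 differed by 0.29 ± 0.181, 0.12 ± 0.109 and -0.14 ± 0.121 and did not pass. For Cd40, the brighter probe set differed by 0.66 ± 0.133 and missed the threshold (adjusted p = 0.0567). Of the genes named here, Slco5a1, Serpinb9, Il15ra, Cd200, Cd80, Cd86, Cd83 and Cd40 lie outside the naming rule. The list's median log2 difference was 1.06 (camera adjusted p = 1.48e-32), with an adjusted p = 0.137 with an estimated correlation. Without wild-type replicate 1, 12 members were called and without knockout replicate 1, 11. The handling and heat shock list, described below, had a median of -0.46 in the same comparison.

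Ligands, cytokines and enzymes by which dendritic cells act on regulatory T cells rose in 4 of 27 members and fell in 0, with 9 higher and 2 lower when adjusted over the list alone. The 4 were Il6, Tnfsf4, Ccl22 and Cd70, all of which also stand in the maturation list. The median was 0.18 (camera adjusted p = 5.50e-05; adjusted p = 0.137 with an estimated correlation). Ccl22 and Tnfsf4 were not called without wild-type replicate 1, nor Ccl22 and Cd70 without knockout replicate 1 (highest limma adjusted p = 0.0706 and 0.0685).

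NF-kB targets and inflammatory cytokines moved in both directions, with 4 of 26 higher and 3 lower, or 8 and 5 when adjusted over the list alone. Il6, Cxcl2, Cxcl1 and Traf1 rose, Cxcl2 by 1.18 ± 0.105. Cxcl1 lay above background in 2 knockout and 0 wild-type arrays. Ccl3, Ccl4 and Tnf fell, by 1.81 ± 0.230, 1.14 ± 0.170 and 0.77 ± 0.104. The median was 0.23 (camera adjusted p = 0.00755; adjusted p = 0.319 with an estimated correlation), and camera's adjusted p was 0.337 above the median level, 0.0985 above background, 0.0732 without wild-type replicate 3 and 0.0562 without both arrays numbered 3. Without wild-type replicate 1, limma called neither Ccl3, Ccl4, Cxcl1, Tnf nor Traf1 (highest adjusted p = 0.113), and without knockout replicate 1 neither Cxcl1, Tnf nor Traf1 (highest 0.138). Traf1 was lost with any 1 array left out (lowest 0.0792) and with the mean of its probe sets (0.135).

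Of the dendritic cell subset lists, camera called pDC higher and cDC2 and cDC1 lower, the last without a passing gene. With an estimated correlation it called none (adjusted p = 0.534, 0.655 and 0.655). The cDC2 and cDC1 medians were not shown to differ (two-sided permutation of genes, p = 0.423). Among 16 pDC markers, 5 rose and 0 fell, with 10 higher and 1 lower when adjusted over the list alone. These were Cox6a2, Atp1b1, a subunit of the sodium pump, Cd209d, and the transcription factors Spib and Tcf4, with increases of 3.04 ± 0.250, 2.20 ± 0.325, 0.99 ± 0.150, 1.29 ± 0.20 and 0.76 ± 0.133. Tlr7, also on the list, differed by -1.38 ± 0.291 (limma adjusted p = 0.0663). The median was 0.76 (camera adjusted p = 1.73e-07). The number of higher pDC markers was 1 without wild-type replicate 1 or knockout replicate 2, 2 without knockout replicates 1 or 3, 3 without wild-type replicate 2, 10 without wild-type replicate 3, and 1 without both arrays numbered 2.

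Among 23 cDC2 markers 3 fell and 0 rose, with 12 lower and 2 higher when adjusted over the list alone. Dtx1 fell by 2.11 ± 0.187, Hes1, a Notch target, by 0.83 ± 0.123 and Cd209a, a lectin, by 0.61 ± 0.106. Sirpa and Cd4 differed by -0.68 ± 0.146 and -0.90 ± 0.216 and did not pass. The median was -0.39 (camera adjusted p = 5.50e-05; adjusted p = 0.655 with an estimated correlation). The number of lower cDC2 markers was 1 without wild-type replicate 1, knockout replicate 1, knockout replicate 2 or both arrays numbered 2, and 2 without wild-type replicates 2 or 3. Cd209a was not called with any 1 array left out, nor Hes1 without wild-type replicate 1 or knockout replicates 1 or 2. Of 19 cDC1 markers 0 passed, and 2 were higher and 3 lower when adjusted over the list alone. The cDC1 median was -0.20 (camera adjusted p = 0.0374; adjusted p = 0.655 with an estimated correlation), and Id2 and Cd36 differed by 0.48 ± 0.115 and -0.74 ± 0.177. Camera's adjusted p for cDC1 was 0.132 and 0.109 without wild-type replicates 2 and 3, and 0.0595 and 0.120 without knockout replicates 2 and 3. It was 0.153 and 0.203 without both arrays numbered 2 and 3, 0.0917 above the median level and 0.0749 above background.

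**Figure D3:**
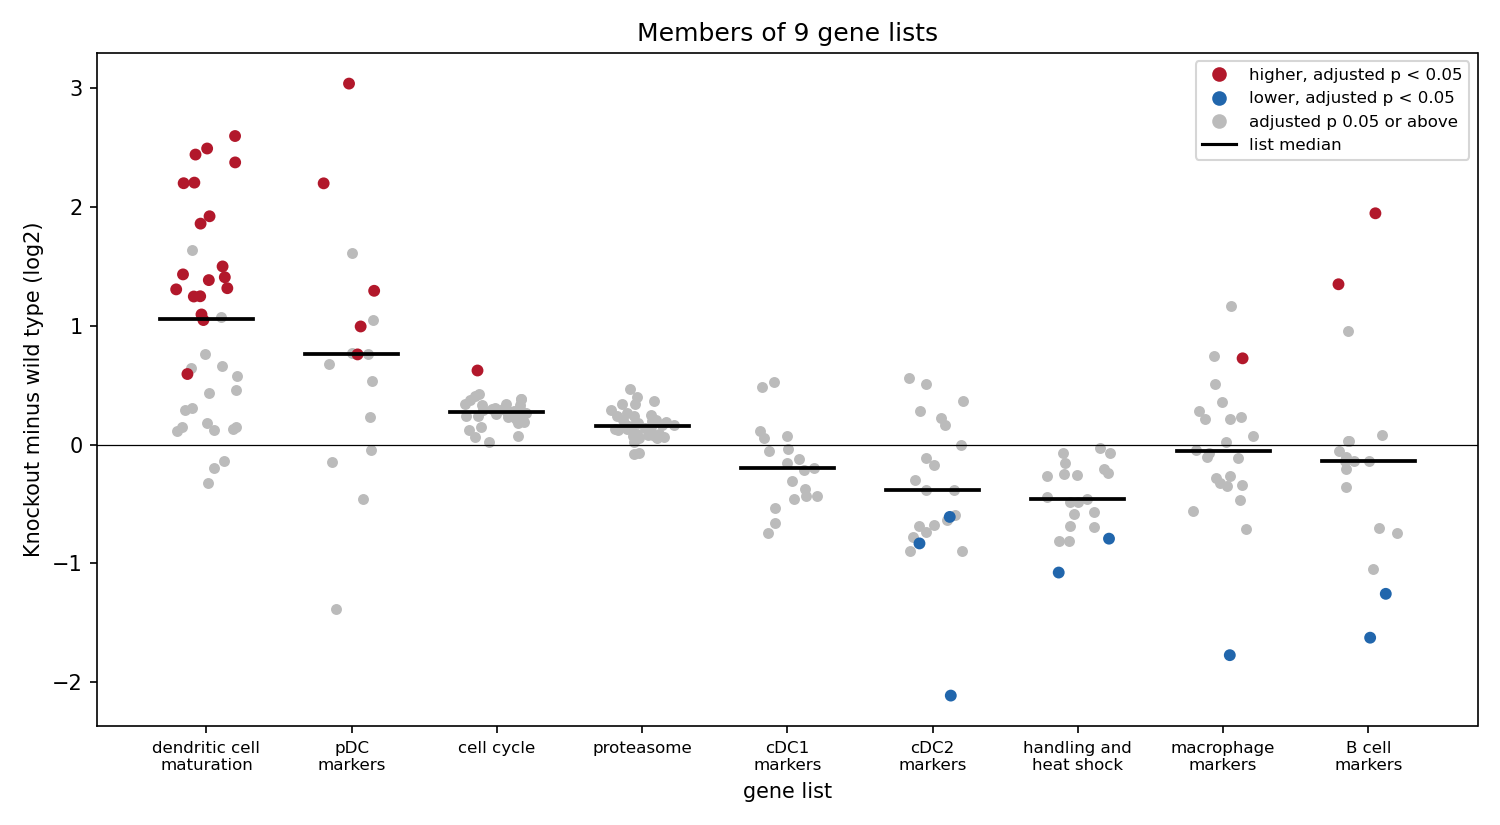
Each point is a gene of 1 of 9 lists (x axis), with its log2 difference, knockout minus wild type, on the y axis, red where higher and blue where lower at a limma adjusted p under 0.05, and grey otherwise. Black bars are list medians, which lay at 1.06 for maturation, 0.76 for pDC, -0.39 for cDC2 and -0.46 for handling and heat shock genes.

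Single B cell and macrophage markers changed, although the sort removed CD19-positive cells. Of 18 B cell markers, Cxcr5 was at least 2.86-fold higher, Blnk rose by 1.35 ± 0.245, and Bank1 and Cd22 fell by 1.26 ± 0.157 and 1.63 ± 0.207, with 3 higher and 4 lower when adjusted over the list alone. Cd79b, a receptor component, differed by 0.03 ± 0.299. Without wild-type replicate 1, Blnk, Cd22 and Cxcr5 were not called (highest limma adjusted p = 0.180), nor were Blnk and Cd22 without knockout replicate 1 (0.179). Blnk was also lost without wild-type replicate 2 (0.0607) and knockout replicates 2 and 3 (0.119 and 0.0920). Of 24 macrophage and monocyte markers, Adgre1 fell by 1.77 ± 0.222 and Lyz2, lysozyme, rose by 0.72 ± 0.139, with 3 higher and 3 lower when adjusted over the list alone. Lyz2 was not called in any fit with 1 array left out (lowest adjusted p = 0.0868). It was also lost with robust empirical Bayes and with array medians subtracted (limma adjusted p = 0.05025 and 0.07286). Cd68 differed by -0.32 ± 0.117. Camera called neither list (adjusted p = 0.266 and 0.988), but without both arrays numbered 2 it called the B cell list lower (median -0.195, adjusted p = 0.0345).

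Of 21 neutrophil, eosinophil and mast cell markers, Mmp9 fell by 1.37 ± 0.119, also when adjusted over the list alone, and 3 had a positive difference. The median was -0.25 (camera adjusted p = 0.00755; adjusted p = 0.655 with an estimated correlation), and without wild-type replicate 1 it was -0.15 (camera adjusted p = 0.0680). It was -0.15 without wild-type replicate 3 (0.0139), and without both arrays numbered 3 camera's adjusted p was 0.0663. S100a9 and S100a8 differed by -0.79 ± 0.345 and -0.86 ± 0.426 and did not pass. Limma called 0 T cell, natural killer, erythroid and platelet or stromal markers, among 19, 18, 19 and 19 measured. Adjusted over the list alone, 0 T cell markers passed, 1 natural killer and 2 erythroid markers were lower, and 2 stromal markers were higher and 1 lower. Their brightest members Cd247 (0.32 ± 0.144), Cd5 (-0.11 ± 0.20), Ccl5 (0.13 ± 0.198), Klrd1 (-0.13 ± 0.156), Hba-a2 (-0.02 ± 0.10), Hbb-b2 (-1.15 ± 0.296), Pecam1 (-0.58 ± 0.209) and Kdr (0.58 ± 0.128) did not pass. Camera's adjusted p was 0.765 for T cells, natural killer cells and stroma and 0.722 for erythroid cells. Of the sex genes, Xist read 11.26 in wild type and 11.01 in knockout, Kdm5d read 4.68 and 4.80, above background in 1 wild-type and 3 knockout arrays, and Uty and Eif2s3y lay in the background in both. Kdm5d differed by 0.118 (limma adjusted p = 0.842). The highest background control was 4.39 to 4.98 in wild-type and 3.96 to 4.62 in knockout arrays, so the count of arrays does not show a higher Kdm5d signal.

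Immediate early and heat shock genes, which respond to tissue digestion and sorting, were lower in the knockout. Of 21 members 0 had a positive difference, 2 fell, and 8 fell when adjusted over the list alone. The transcription factors Egr2 and Egr1 fell by 1.08 ± 0.111 and 0.79 ± 0.120, and Nr4a1 and Atf3 differed by -0.69 ± 0.139 and -0.81 ± 0.217. The median was -0.46 (camera adjusted p = 1.73e-07; adjusted p = 0.608 with an estimated correlation). It was -0.28 and -0.20 without wild-type and knockout replicate 2, and -0.15 without both (camera adjusted p = 0.142). Egr1 was not called without wild-type replicates 1 or 2 or knockout replicates 2 or 3 (limma adjusted p = 0.0934, 0.0582, 0.0747 and 0.0624).

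Cell cycle genes were higher by a small amount: all 35 had positive differences, with a median of 0.27 (camera adjusted p = 1.53e-10; adjusted p = 0.439 with an estimated correlation). Only Nusap1, a spindle protein, passed for itself, also when adjusted over the list alone (0.63 ± 0.0990), and its limma adjusted p was between 0.0618 and 0.0998 with any 1 array left out. Of 37 proteasome subunits, 35 had positive differences, 0 passed (0 adjusted over the list alone) and the median was 0.16 (camera adjusted p = 4.37e-05; adjusted p = 0.885 with an estimated correlation). That median was 0.06 without wild-type replicate 2, and 0.25 and 0.08 without knockout replicates 2 and 3. Of 20 p53 targets and apoptosis genes, the cell cycle inhibitor Cdkn1a, the death receptor Fas, the pro-apoptotic Bcl2l11 and the anti-apoptotic Bcl2l1 rose, Cdkn1a by 1.49 ± 0.163, with 5 higher and 1 lower when adjusted over the list alone and no camera call (adjusted p = 0.104). Fas, above background in 1 of 3 wild-type arrays, was not called without wild-type replicate 1 or knockout replicates 1 or 2 (highest limma adjusted p = 0.0736). Bcl2l11 was lost in these fits and without knockout replicate 3 (highest 0.110), and Bcl2l1 with any 1 array left out (highest 0.175) and with an intensity trend (0.0541).

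The metabolic lists had smaller median differences than the maturation list, and the lists were not tested against each other. Of 23 glycolysis genes, Eno2, a neuronal enolase, and Pfkfb3, which makes an activator of phosphofructokinase, rose by 2.21 ± 0.155 and 1.01 ± 0.136, and the glucose transporter gene Slc2a3 fell by 1.09 ± 0.164, with 5 higher and 2 lower when adjusted over the list alone. The median was 0.15 (camera adjusted p = 0.0382; adjusted p = 0.885 with an estimated correlation), and camera's adjusted p was 0.192 without wild-type replicate 2, where the median was 0.07, and 0.0944 and 0.147 without knockout replicates 1 and 3. It was 0.132 by ranks, 0.0917 above the median level, 0.0749 above background, 0.0600 with the mean of the probe sets and 0.0530 without both arrays numbered 3. Without knockout replicate 2 the median was 0.26. Pfkfb3 and Slc2a3 were not called without wild-type replicate 1 or knockout replicate 1 (highest limma adjusted p = 0.0959 and 0.0962), nor Slc2a3 without wild-type replicate 2 or knockout replicate 2 (0.0503 and 0.0546). Of 24 genes of sterol and fatty acid synthesis, Idi1 and Fads2 rose by 1.15 ± 0.133 and 0.81 ± 0.130 (2 also adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.00586; adjusted p = 0.655 with an estimated correlation) that was 0.03 without knockout replicate 3 (camera adjusted p = 0.167) and 0.07 without both arrays numbered 3 (0.132). Fads2 was called only when no array or knockout replicate 3 was left out (limma adjusted p up to 0.126 without knockout replicate 1). Of 22 NRF2 targets, the cystine transporter gene Slc7a11, at least 2.67-fold, Txnrd1 and Srxn1 rose (4 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.00645; adjusted p = 0.655 with an estimated correlation) that was 0.11 without knockout replicate 3 (camera adjusted p = 0.0562) and 0.05 without wild-type replicate 2 (0.0265). Srxn1 was not called with any 1 array left out (highest limma adjusted p = 0.171, without wild-type replicate 1), nor Txnrd1 without knockout replicate 1 (0.0578). Srxn1 was also lost with an intensity trend, with array medians subtracted and after quantile normalization (limma adjusted p = 0.06449, 0.06375 and 0.05235).

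Camera called no other metabolic list. Limma called 3 of 22 HIF-1 targets (Mxi1, Pfkfb3 and Ndrg1, all higher; 3 adjusted over the list alone; camera adjusted p = 0.447), and Ndrg1 and Pfkfb3 not without knockout replicate 1 (highest 0.0784), nor Ndrg1 without knockout replicate 2 (0.0527). It called 1 of 79 respiratory chain genes (Cox6a2, 1 over the list alone; 0.397) and 1 of 24 ATF4 targets (Slc7a11, 1 over the list alone; 0.231). Of tricarboxylic acid cycle genes (23; 0.765), fatty acid oxidation genes (20; 0.524), LXR targets (10; 0.980), MYC and ribosome biogenesis genes (27; 0.765) and unfolded protein response genes (23; 0.737), 0 passed, also 0 adjusted over the list alone. Cytosolic ribosomal proteins had 1 call in 70 (Rps27l; 0.722) and mitochondrial ones 1 in 73 (Mrpl38; 0.765), both higher and each also over its list alone. Among all 17097 genes in the list test 1.70% were called higher, so 1 call in 70, 73 or 79 genes is not above that share. Limma lost Rps27l without knockout replicate 1 (0.0614), and Mrpl38 without wild-type replicates 1 or 2 or knockout replicates 1 or 3 (0.0988, 0.0516, 0.0962 and 0.0534) and with the mean of its probe sets (0.241). Of 20 measured members of the LKB1 and AMPK kinase list, which also holds partners and regulatory subunits, Stk11 alone was called, also over the list alone (camera adjusted p = 0.966). Of 21 CREB and CRTC targets 0 passed, and 3 were lower when adjusted over the list alone (median -0.113; 0.104). Camera called this list lower above the median level (-0.223, adjusted p = 0.0356), without wild-type replicate 3 (-0.229, 0.00190), without knockout replicate 1 (-0.193, 0.0238) and without both arrays numbered 3 (-0.235, 0.0241). As fixed, it shares Fos, Fosb, Junb, Atf3, Dusp1 and Nr4a1 with the handling and heat shock list, so its values do not stand apart from that list's.

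Among 22 antigen presentation genes, H2-Ob and H2-Oa, the chains of H2-O that restrains peptide loading of MHC class II, fell by 1.31 ± 0.158 and 0.84 ± 0.150, with 3 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.980). Without knockout replicate 1 neither was called (highest limma adjusted p = 0.142). With 1 array left out, H2-Oa passed only without wild-type replicate 2, and it was also lost with array medians subtracted (0.05579). Of 31 interferon-stimulated genes, Gbp2 rose by 2.04 ± 0.260, also over the list alone (camera adjusted p = 0.650), with a limma adjusted p of 0.0617 without knockout replicate 1. Of 34 lysosome and autophagy genes, the protease gene Ctsl and the membrane protein gene Lamp1 rose by 1.47 ± 0.232 and 0.92 ± 0.147 (2 also over the list alone; camera adjusted p = 0.447). Both were lost without wild-type replicates 1 or 2 or knockout replicates 1 or 2 (highest limma adjusted p = 0.124, 0.0667, 0.114 and 0.0837), Lamp1 also without knockout replicate 3 (0.0775) and Ctsl with the mean of its probe sets (0.0861).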

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

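Leaving out both arrays of a number and the filter on background were chosen after seeing the data. The count of 854 calls (608 higher, 246 lower) ranged from 272 to 755 with any 1 array left out (226 to 574 higher, 42 to 219 lower), where fewer samples were fitted, and 0 of these calls turned in any setting that tested probe sets. It was 371 without both arrays numbered 2 (300 higher, 71 lower), 479 without both numbered 3 (364 and 115), 2287 with array weights (1306 and 981, or 57.1% higher against 71.2%) and 1351 at an adjusted p under 0.1 (457 lower). The array weights were 2.242 and 2.732 for wild-type and knockout replicate 1 and 0.563 to 0.769 for the other arrays. The weighted count thus leans on the arrays numbered 1. With 1 probe set per gene, where fewer were tested, 381 were higher. The other settings gave between 758 and 941 probe sets, or 576 and 629 when genes were tested. The replicate block, limma's fit with the replicate number as a term, called 1718 (1072 higher, 646 lower), all 854 among them. Deviations of same-numbered arrays correlated at 0.052, 0.489 and 0.417 for numbers 1, 2 and 3, and 5 of 6 arrays correlated best with their own number, a hint from the data and not from the design. Deviations from a genotype's mean cancel out over its arrays, so these values do not stand independently of each other. The causes of these moves were not tested unless stated.

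Stk11 lay between -0.929 and -0.708 with 1 array left out, and it did not pass at -0.815 with array medians subtracted, -0.360 with the mean of its probe sets, -0.924 without both arrays numbered 2 or -0.880 without both numbered 3. Maturation genes called higher numbered 11 to 20 with 1 array left out, pDC markers called higher 1 to 10 and cDC2 markers called lower 1 to 4. Without both arrays numbered 2, pDC and cDC2 markers had 1 call each, and cDC2 markers had 6 with the mean of the probe sets of a gene and 10 with the replicate block. Camera called 13 lists, against 0 with an estimated correlation, 4 by fry for direction (maturation, regulatory T cell ligands, NF-kB and p53 targets) and 24 by fry for change either way. Lists without a main call gained one in some settings: CREB and CRTC targets (-0.223 above the median level, -0.229 without wild-type replicate 3, -0.193 without knockout replicate 1, -0.235 without both arrays numbered 3), B cell markers (-0.195 without both arrays numbered 2), the respiratory chain (0.125 without wild-type replicate 3, 0.132 without knockout replicate 2), the mitochondrial ribosome (0.104 and 0.126 in the same fits), the interferon response (0.198 without wild-type replicate 3), and ATF4 targets (0.205) and the unfolded protein response (0.120) without knockout replicate 2. Of the 87 called genes in the text, 36 passed in each fit with 1 array left out and 51 were lost in at least 1, and no called gene or list turned its direction in any setting.

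What turned direction were lists and genes that were not called, and camera or limma called 1 of them when turned, the mitochondrial ribosome without wild-type replicate 2. Values are median or single log2 differences, and a list's test and median can differ in sign. With 1 array left out, the lowest and highest were -0.023 and 0.023 for antigen presentation, -0.086 and 0.059 for LXR targets, -0.058 and -0.006 for the cytosolic ribosome, -0.093 and 0.044 for erythroid markers, -0.083 and 0.125 for fatty acid oxidation, -0.129 and 0.198 for the interferon response, -0.012 and 0.056 for LKB1 and AMPK kinases, -0.095 and 0.090 for MYC targets, -0.126 and 0.046 for macrophage markers, -0.148 and 0.126 for the mitochondrial ribosome, -0.039 and 0.068 for natural killer markers, -0.088 and 0.132 for the respiratory chain, -0.104 and 0.027 for the tricarboxylic acid cycle, -0.017 and 0.039 for T cell markers and -0.072 and 0.122 for the unfolded protein response. For single genes they were -0.076 and 0.334 for Ccl5, -0.314 and 0.065 for Cd5, -0.286 and 0.334 for Cd79b, -0.309 and 0.088 for Esam, -0.054 and 0.017 for Hba-a2 and -0.256 and 0.015 for Klrd1.

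Other settings turned LKB1 and AMPK kinases (0.012 by fry, -0.008 above the median level, -0.036 with the mean of the probe sets, -0.020 above background), antigen presentation (0.014 by fry, -0.027 with the mean of the probe sets), LXR targets (-0.037 by ranks and with the replicate block, -0.044 after quantile normalization, -0.023 without the arrays numbered 2) and macrophage markers (-0.063 with medians subtracted, -0.062 after quantile normalization, -0.058 with the replicate block, 0.117 without the arrays numbered 3). Natural killer markers turned above the median level (-0.13) and above background (0.002). Without the arrays numbered 2, the tricarboxylic acid cycle (-0.031), T cell markers (-0.036), Cd79b (-0.187) and Ccl5 (-0.124) turned, and without those numbered 3, MYC targets (-0.014), erythroid (0.065) and stromal markers (0.012). Cd79b turned with array weights (-0.079) and Kdm5d with the mean of its probe sets (-0.034). Signals near background limit the dim probe sets: 11251 lay in the background on every array, and 8 calls had both groups there.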

Other observations

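The genes in this paragraph were chosen after their values were seen. Of 20 measured semaphorin genes, by the brightest probe set of each, limma called 3 higher and 0 lower, and 17 did not pass. By the probe set with the smallest p, Sema6d rose by 1.47 ± 0.117 log2 units (SE), Sema7a by 0.89 ± 0.129 and Sema4a by 0.78 ± 0.128, while Sema4d fell by 0.77 ± 0.115 (adjusted p = 0.00198, 0.0156, 0.0263 and 0.0177, n = 3 arrays each). Of 4 Sema6d probe sets 2 passed, of 2 Sema7a probe sets 1 and of 2 Sema4d probe sets 1, with the others differing the same way. With 1 array left out, Sema6d passed each time, Sema4a only without wild-type replicate 3 (adjusted p up to 0.125), Sema7a not without wild-type replicate 1 or knockout replicates 1 or 3 (0.0766, 0.0912 and 0.0523), and Sema4d not without wild-type replicate 1 or knockout replicates 1 or 2 (0.10, 0.0871 and 0.0657). The Notch-associated Dtx1 and Hes1 fell, while Esam, another Notch-dependent cDC2 gene, differed by -0.11 ± 0.224. Il12b, a cytokine chain made by mature dendritic cells, passed by 1 of its 2 probe sets (1.17 ± 0.219, adjusted p = 0.0429) and not by the other (1.07 ± 0.285, 0.148).

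The tests below were set before their results were seen, but the split of the deviations by level and the choice of H2-Ea as a place to test came after the deviations of the arrays had been looked at. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many calls as the 854 of the real split, which was the real one, and the highest of the others gave 0. Splits of 3 against 3 are too few for a share under 0.05. At an unadjusted p under 0.05, limma gave 5042 probe sets in the real split and 5805 in the split that set both arrays numbered 3 with wild-type replicate 1 against the rest. At each replicate number the knockout array had more probe sets above background. Its highest background control, which sets that share, was lower. The ranges of both overlapped between the genotypes. The 3' minus 5' signal of beta-actin was higher in every knockout array than in any wild-type array. What part they have in the calls was not tested.

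Maturation genes were higher in the knockout. Stress of digestion and sorting would have raised the handling and heat shock list. Its median was -0.458 (bootstrap 95% interval over members -0.583 to -0.244), so the list was not higher in these arrays. That interval holds no spread between arrays, and the members vary together (estimated correlation 0.449, with which camera's adjusted p was 0.608). The test therefore does not decide on stress. With any 1 array left out the interval's upper end stayed below 0 and the median lay between -0.534 and -0.201, the weakest without knockout replicate 2 and next -0.277 without wild-type replicate 2. Without both arrays numbered 2, a setting chosen after seeing the data, the median was -0.150 (interval -0.320 to 0.207, camera adjusted p = 0.142), which does not clear the bound of 0.1 set against this cause. A larger share of mature cells among the sorted cells stays open: 6 measured transcripts near exclusive to such cells had a median of 1.82, between -0.32 for Apol7c and 2.49 for Fscn1. The Apol7c value rested on knockout replicate 3, without which it was 1.01, and without knockout replicates 1 or 2 it was -0.93 and -1.04. Ccr7, which was to decide this, was not analysed here. A change within each cell through the loss of LKB1 stays open beside it, untested.

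Adgre1, Cd22 and Dtx1, genes shared with macrophages, B cells or cDC2, fell in the knockout. They were picked for falling, and Lyz2, Cxcr5 and Blnk, of the macrophage and B cell lists, rose. Fewer B cells would have lowered the whole B cell list, whose median without Cd22 was -0.135 (interval -0.360 to 0.032). This stays open, because the interval includes the bound of -0.2 set for the test, and the median was -0.187 (interval -0.536 to -0.016) without both arrays numbered 2 and -0.049 (interval -0.184 to 0.141), above that bound, without both numbered 3, settings chosen after seeing the data. The sort removed CD19-positive cells. Fewer red pulp macrophages would have lowered C1qa, C1qb, C1qc, Vcam1, Spic, Cd5l and Slc40a1. Their median was 0.213 (interval over genes -0.102 to 0.234), so these genes argue against it in these arrays. That interval holds no spread between arrays, and it was not rerun with arrays left out. A lower share of cDC2 and a fall within cells would both lower cDC2 markers against cDC1 markers, so this contrast cannot tell them apart. The cDC2 median lay -0.187 from the cDC1 median, between the bounds set for the test. The two-sided permutation p = 0.423 shuffled 42 genes and does not measure the spread between arrays. The genotype's own effect on these genes was not tested apart from cell shares.

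Arrays numbered 2 deviated together from their genotype means, and so did those numbered 3, with correlations of 0.607 and 0.579 over the 11259 brightest probe sets and 0.190 and 0.131 over the dimmest. Deviations from a genotype's mean cancel out over its arrays, so numbers 2 and 3 may reflect the same shared pattern. Over all probe sets, replicates 2 and 3 correlated at -0.748 in wild type and -0.732 in knockout. Among these deviations H2-Ea, a class II gene that the C57BL/6J reference lists as a transcribed pseudogene, stood out after its values were seen: of its 3 probe sets, 1 read 9.99 and 9.15 in the wild-type and knockout arrays numbered 2 and between 4.94 and 5.53 in the other arrays. The second read 10.01 and 9.18 there and between 4.16 and 4.94 elsewhere, and the third 4.79 and 3.72 against 3.07 to 3.58. All samples are labelled C57BL/6. A strain difference around H2-Ea stays open. Among genes above the median level, the 20 on either side of H2-Ea had a mean shared deviation of 0.118. This lay at the 97.6 percentile of 465 overlapping windows of 40 neighbouring genes. The score took the size of a shared deviation and not its direction. The windows were not matched for level, while bright probe sets shared more of the deviations, so the percentile cannot decide. The high H2-Ea signal lies in 1 array of each genotype. Cells of another type would have moved a list of their markers oppositely in the arrays numbered 2 and 3 of both genotypes. The largest such deviation that each of these arrays reached was 0.001. In wild type alone some lists did move. The pDC markers deviated by -0.274 and 0.414 in wild-type replicates 2 and 3, against 0.019 and -0.024 in knockout replicates 2 and 3. The 3' to 5' control ratios differed by at most 0.0600 between these arrays, too little to decide on RNA quality. What the shared deviations come from stays open.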
